A study of Mus musculus with 5 samples.

How the data were processed

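Gene expression was measured by bulk RNA sequencing in 5 mouse libraries of sorted common lymphoid progenitors (lineage-negative, CD127-positive and Flt3-positive bone marrow cells), 3 of the SF1 genotype and 2 wild type (WT). Per the labels' protocols, marrow was harvested 16 weeks after tamoxifen, RNA was isolated with a column kit for small samples, only RNA with a RIN (an index of RNA integrity) above 7 was used, and the SMART-Seq chemistry (version 2 or 4) gave the cDNA for Nextera XT libraries. Which libraries used which SMART-Seq version, and whether a library came from 1 animal or from a pool, is not given in the sources used here. This amplification copies full-length polyadenylated RNA from few cells, has no molecular identifiers and does not mark the strand. PCR copies are therefore counted as reads, and reads of a gene cannot be told apart from those of an overlapping or antisense gene. Counting intervals and floors given here cover counting error only.

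The authors deposited 1 table of raw counts per gene, with no normalization. Per the submitters' processing notes, FastQC, HISAT2 2.2.1 and featureCounts 2.0.1 were used with the GRCm38 build of the mouse genome. The annotation release, the strand setting and the treatment of reads that match several places are not given in the sources used here. Genes with near-identical copies, such as the alpha-globin genes Hba-a1 and Hba-a2, share reads, so their separate values are uncertain. Of the 55487 gene identifiers in the table, 55227 matched the GENCODE M21 annotation of the same build, which gave symbols and coordinates. The other 260 hold 0.0123% of all counts and keep their identifiers.

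Total counts were 9350767, 11290082 and 10730820 in SF1 replicates 1, 2 and 3, and 20424296 and 8894288 in WT replicates 1 and 2. A count of 1 therefore stood for between 0.049 and 0.112 CPM (counts scaled to the same total per library), and a floor of 3 counts for between 0.147 and 0.337 CPM. WT replicate 1 was the deepest, so all libraries were also thinned to the smallest total. No pair of libraries was a repeat of the same library: chi-square per degree of freedom over genes was between 6.38 and 8.81 within groups, above the value near 1 that sampling noise gives.

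Genes were tested for a difference between SF1 and WT with edgeR 4.0.16 (R 4.3.3), using TMM scaling, the filterByExpr filter (minimum count 10) and the quasi-likelihood F test, with no covariate. P-values were adjusted over all genes tested by the Benjamini-Hochberg method, with a threshold of 0.05. All adjusted p-values of single genes are from this test unless another is named. Log2 fold changes are SF1 over WT, with the standard error (SE) derived from the F statistic. Levels are TMM-scaled CPM, as mean ± SD over libraries. The biological coefficient of variation was 0.122. A gene whose counts in 1 group sum to 0 is given as a bound against 3 counts over the group, and a gene with 1 to 3 counts there as the ratio of summed CPM with a 95% counting interval.

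In all, 27 gene lists holding 632 different genes were fixed before the data were examined, from textbook lineage markers and pathways. They include markers of cell types that the sort could also hold. 21 genes are in more than 1 list. Each list was tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01 between genes, adjusted over the 27 lists, and again with a correlation estimated from the data and with fry, which asks only whether the genes of a list move 1 way. For each list the number of genes past the threshold is given over all genes tested and adjusted over the list alone. Genes are named by a rule fixed at the same time: the 12 higher and the 12 lower genes with the smallest p among those with an adjusted p under 0.05, separated ranges of the groups and a mean of at least 5 CPM, leaving out predicted genes, pseudogenes, mitochondrial and ribosomal protein genes and immunoglobulin segments; up to 4 members of each list with the smallest p; and Jak2, Il7r, Flt3, Kit, Ly6a, Ebf1, Pax5, Socs1, Socs2, Socs3, Cish and Pim1. Other genes named in the text were chosen after their values were seen.

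The tests were checked on simulated counts with the real means and library sizes. For SF1 against WT with 14137 simulated genes, the edgeR test recovered 20% of the genes changed by 0.5 on the log2 scale, 69.4% at 1, 95.8% at 2 and 100% at 3. Of its 146 calls, 7 were false. Between 48 and 50 genes were changed at each size, and counts were drawn independently for each gene. The share of false calls in the real comparison, with 2382 calls, is therefore not known from it. With a simulated GC trend over 14178 genes, 2888 of 3043 calls were false before and 13 of 152 after the trend was removed. That trend was linear, the same in each SF1 library, without a length trend and steeper than the one in the data. It therefore does not show how well the correction works on these libraries.

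Alternatives were DESeq2 size factors, library-size scaling, no filter, a stricter filter (5 CPM in 2 libraries), DESeq2 1.42.0, limma voom without and with sample weights, each library left out in turn, and the replicate number as a block. The fit with no filter tested 26875 genes instead of 14423. It gave Ebf1, Jak2 and Socs3 smaller adjusted p-values at nearly the same fold changes, so its p-values are not read as stronger evidence. Leaving out a WT library leaves 1, whose spread is then assumed to be that of the SF1 libraries. There is no WT replicate 3, so the block takes SF1 replicate 3 out of the group comparison. Its results are therefore close to those without SF1 replicate 3 and are not a separate check. A correction of each library for the trend of expression with GC content and length (loess, span 0.5), and the thinning to equal totals, were added after the data were seen. With 3 libraries against 2, an exact permutation test of any single value cannot go below a two-sided p of 0.1, so differences are judged by the models fitted across all genes. All 5 libraries were used, and no sample was left out.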

Results

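Common lymphoid progenitors (CLPs) are the bone marrow cells from which B, T and natural killer cells arise. Their RNA was sequenced from SF1 mice, which carry SclCre and the kinase mutant JAK2-V617F common in myeloproliferative neoplasms, and from wild-type (WT) mice, 16 weeks after tamoxifen. The series asks how this mutant affects lymphoid differentiation, and its design sets 3 SF1 libraries against 2 WT libraries. Total counts were between 9350767 and 11290082 in the SF1 libraries and were 20424296 and 8894288 in WT replicates 1 and 2. Between 20600 and 22749 genes had at least 1 count per library. The labels do not say whether the libraries came from separate animals, so p-values measure the spread between these libraries only. The first principal component held 58.8% of the variance and separated the groups, with SF1 libraries between -37.8 and -16.4 and WT libraries at 40.5 and 42.9.

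The sorted SF1 libraries had higher RNA of most neutrophil and dendritic genes than the WT libraries, and lower RNA of part of the B-lineage and erythroid genes. Of 14423 genes tested, 977 were higher and 1405 lower in SF1, 2382 in all, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The change was at least 2-fold for 401 of the higher and 234 of the lower genes. In all 2382 the SF1 and WT libraries did not overlap, as was so for 49% of the genes tested, against the 20% that chance gives. By list, 8 of the 27 fixed gene lists were higher and 7 lower in SF1 (camera with a preset correlation). None of these list calls held with a correlation estimated from the data, where the smallest adjusted p was 0.533. With 5 libraries the smallest unadjusted p of that camera variant over all lists was 0.0519, and its power was not checked on simulated counts. It therefore does not decide for or against any single list. The estimated correlations ran from -0.044 (JAK-STAT targets) to 0.704 (ribosomal protein genes), against the preset 0.01. They were 0.632 for the neutrophil and monocyte list and 0.292 for the B-lineage list, but 0.012 for the glycolysis list. Where the genes of a list move together, the p-values with the preset correlation are too small. The number of changed genes was 986 without WT replicate 1, 1234 without SF1 replicate 2 and 1294 without SF1 replicate 3.

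**Figure D1:**
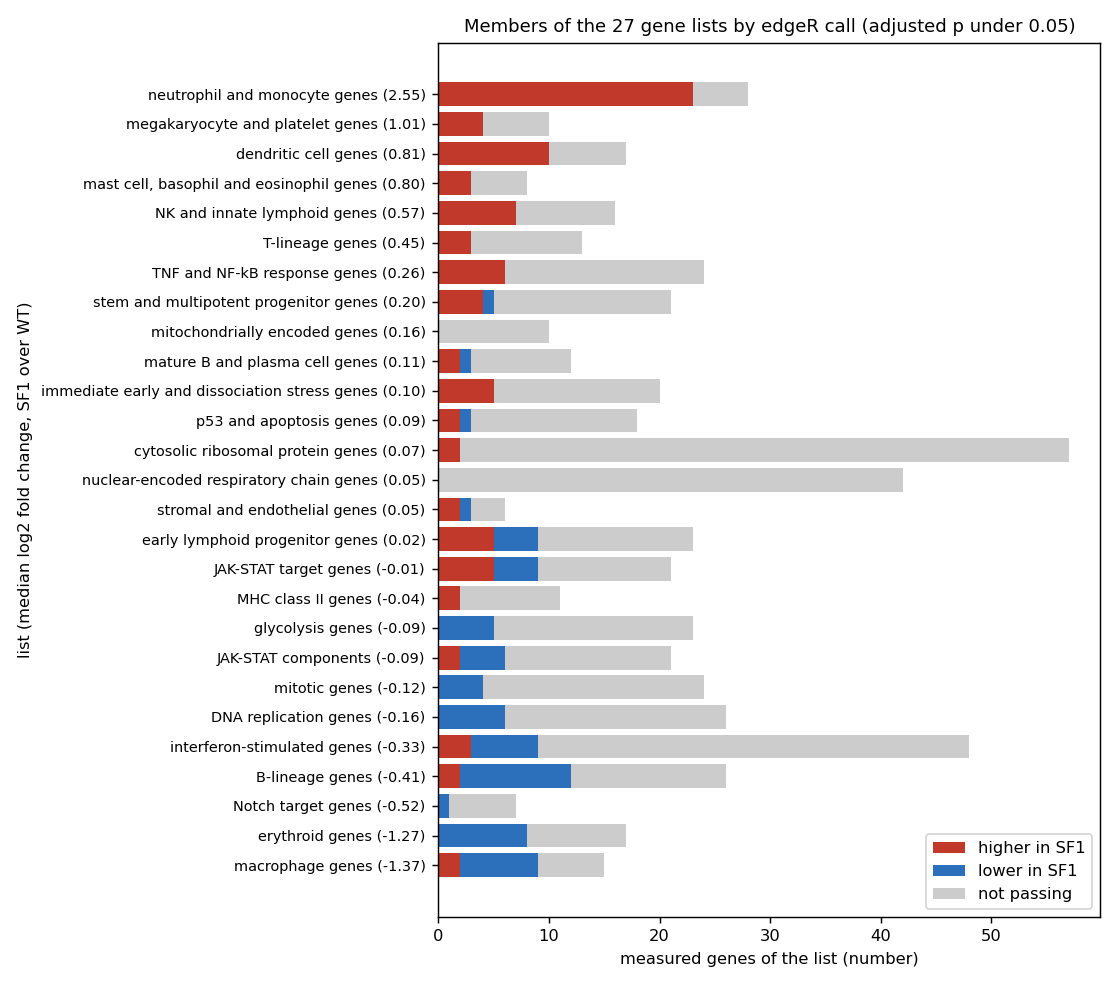
Horizontal bars give, for each of the 27 gene lists, the number of measured genes (x axis) that were higher in SF1 (red), lower in SF1 (blue) or not past the edgeR threshold (grey); the list's median log2 fold change is beside its name. The neutrophil and monocyte list has the highest median (2.55, with 23 of 28 genes higher) and the macrophage list the lowest (-1.37, with 7 of 15 genes lower and 2 higher).

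Jak2, the gene of the genotype, did not pass, nor did Flt3, while Il7r, the other gene of the positive sort, and the stem cell list genes Kit and Ly6a were called. Jak2 (ENSMUSG00000024789, GRCm38 chromosome 19, 29251828 to 29313080) was at 66.4 ± 2.66 CPM (SD, n = 3) in SF1 and at 58.4 and 35.4 CPM in the WT libraries, a log2 fold change of 0.48 (SE 0.18, adjusted p = 0.104). Without WT replicate 1 the log2 fold change of Jak2 was 0.91. With no filter on low counts Jak2 passed (adjusted p = 0.0037), at nearly the same log2 fold change as in the main fit (0.46). Counts per gene do not show the mutation, and whether reads of the mutant are counted under Jak2 is not known. They therefore do not check the genotype. Flt3, the cytokine receptor used in the sort, was at 1644 ± 53.2 CPM in SF1 and 1512 ± 2.13 CPM in WT (n = 3 and 2, log2 fold change 0.12, adjusted p = 0.233), and it passed after GC and length correction (0.24, adjusted p = 0.0364). Il7r, which encodes CD127, rose by a log2 fold change of 0.32 (SE 0.08, adjusted p = 0.0318). This call was lost without any 1 of SF1 replicates 1, 2 and 3 (adjusted p = 0.0739, 0.0665 and 0.0764) or without WT replicate 1 (adjusted p = 0.211), with the replicate number as a block (0.07) and after GC and length correction (0.0559). Kit, the stem cell factor receptor, fell by 0.51 on the log2 scale (adjusted p = 0.0116; 0.0932 without WT replicate 1). Ly6a, which encodes the stem cell antigen Sca-1, rose 2.08-fold, from 37.0 ± 4.70 CPM (n = 2) to 76.4 ± 1.00 CPM (n = 3, adjusted p = 0.000772).

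Part of the B-lineage genes were lower in SF1, among them the B-cell commitment factor Pax5 and the surrogate light chain gene Igll1. Of 26 measured B-lineage genes, 10 were lower, 2 were higher and 14 did not pass, with 10 lower and 2 higher when adjusted over the list alone. Pax5 (chromosome 4, 44524757 to 44710487) was at 16.4 ± 3.19 CPM (SD, n = 3) in SF1 and 36.4 ± 1.67 CPM (n = 2) in WT, 2.23-fold lower (SE of the log2 fold change 0.16, adjusted p = 0.0026). The transcriptional coactivator Pou2af1 was 3.18-fold lower (adjusted p = 0.00206) and Igll1 1.83-fold lower (adjusted p = 0.00241). Ebf1, an earlier B-lineage factor, did not pass, with 198, 92.4 and 103 CPM in the SF1 libraries and 213 and 201 CPM in the WT libraries (adjusted p = 0.127). It passed as lower without SF1 replicate 1 (log2 fold change -1.08, adjusted p = 0.00102), with no filter on low counts (-0.68, adjusted p = 2.49e-10) and by limma voom with sample weights (-0.80, adjusted p = 0.0493). In the main fit its log2 fold change was -0.66, so the far smaller p with no filter does not reflect a larger difference. Higher were Rasgrp3, a signalling exchange factor, by 2.75-fold (adjusted p = 0.00105), and Fcrla, an Fc receptor-like gene (log2 fold change 1.56, adjusted p = 0.0208). The Fcrla call was lost without SF1 replicate 2 or 3 (adjusted p = 0.0759 and 0.0673) or WT replicate 1 or 2 (0.0645 and 0.0806) and with the replicate number as a block (0.0694). The list was lower by camera (median log2 fold change -0.41, adjusted p = 0.00586), with an adjusted p = 0.612 with an estimated correlation. It had 6 genes lower without SF1 replicate 3 and 6 without WT replicate 1, and 1 higher without SF1 replicate 2, SF1 replicate 3, WT replicate 1 or WT replicate 2.

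Early lymphoid progenitor genes went both ways. Of 23 measured, 5 were higher, 4 lower and 14 did not pass, and 6 and 6 when adjusted over the list alone. Ly6d, which marks B-lineage-biased lymphoid progenitors, rose from 521 ± 11.9 CPM (n = 2) to 989 ± 41.3 CPM (n = 3, log2 fold change 0.93, SE 0.07, adjusted p = 0.000232). The chromatin organiser Satb1 rose 1.30-fold (adjusted p = 0.00729). Tcf3 (chromosome 10, 80409514 to 80433647), which encodes the E2A factors needed for B-cell development, fell from 457 CPM (n = 2) to 193 CPM (n = 3; log2 fold change -1.25, SE 0.09, adjusted p = 0.000162). Cnn3, an actin-binding protein gene, fell 1.36-fold (adjusted p = 0.00514). The recombinase gene Rag1 was 2.00-fold lower (adjusted p = 0.0199), a call lost without SF1 replicate 2, SF1 replicate 3 or WT replicate 1 (adjusted p = 0.0799, 0.0707 and 0.14) and by DESeq2 (0.0533). Dntt, which encodes the terminal transferase of lymphoid progenitors, was at a log2 fold change of 0.02 (adjusted p = 0.864). The list did not pass (camera adjusted p = 0.532), and its median of 0.02 and mean of -0.05 differ in sign. Only 2 genes were higher and 2 lower without SF1 replicate 2 or without SF1 replicate 3, and 3 and 2 without WT replicate 1.

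**Figure D2:**
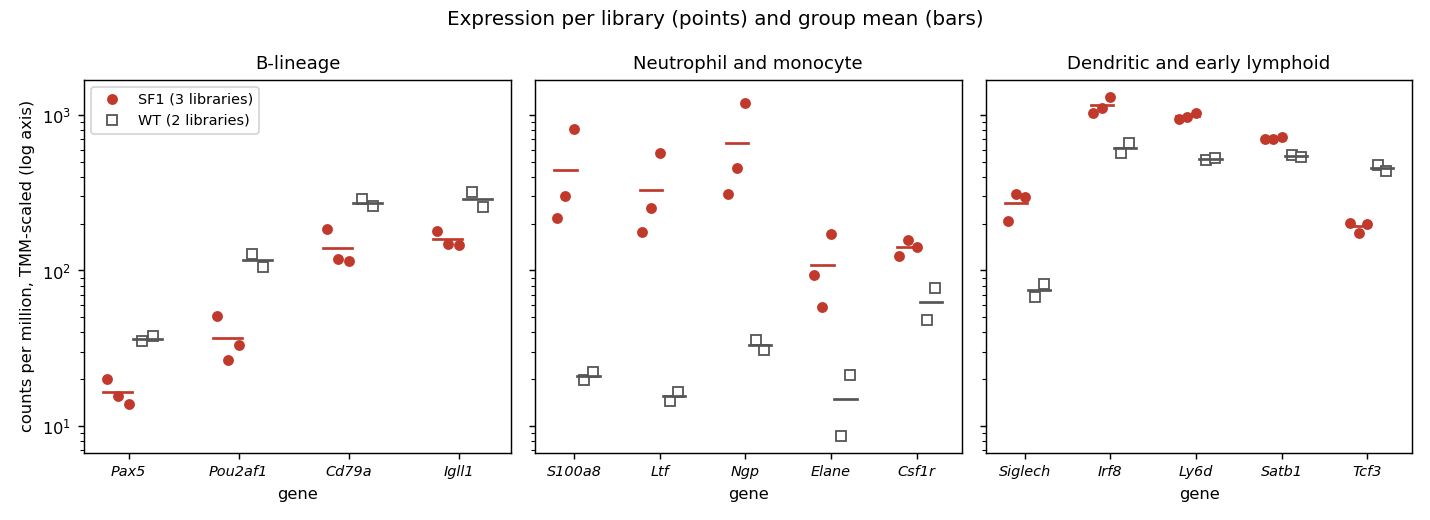
Points give the TMM-scaled CPM of 14 genes in each library on a log axis, red circles for the 3 SF1 libraries and open squares for the 2 WT libraries, and short horizontal bars give the group means. The B-lineage genes lie lower in every SF1 library, while S100a8, Ltf and Ngp lie far higher in SF1 and spread widely there, with S100a8 between 217 and 818 CPM against 19.6 and 22.3 CPM in WT.

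Immunoglobulin constant genes had the largest rise among the called genes named by the rule. Igkc, the kappa light chain constant gene (ENSMUSG00000076609, chromosome 6, 70726435 to 70726966), was at 163 ± 25.1 CPM (SD, n = 3) in SF1 and 0.473 ± 0.185 CPM (n = 2) in WT, a log2 fold change of 8.26 (SE 0.25, adjusted p = 1.43e-06). Igha, the constant gene of immunoglobulin A, was at 226 ± 70.7 CPM and 0.707 ± 0.288 CPM (log2 fold change 8.46, SE 0.44, adjusted p = 5.23e-05). Jchain, which encodes the chain that joins immunoglobulin A molecules, rose 50.6-fold (adjusted p = 0.000395). Ighm, the constant gene of immunoglobulin M, was at 2722 ± 150 CPM in SF1 and 2544 ± 107 CPM in WT (adjusted p = 0.374). The plasma cell gene Mzb1 was at 0.813 ± 0.188 and 1.69 ± 0.676 CPM (adjusted p = 0.196). Of 12 measured mature B and plasma cell genes, 2 were higher (Igkc and Jchain), 1 lower (Cd37, a B-cell tetraspanin, 1.37-fold, adjusted p = 0.00771) and 9 did not pass, with 3 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.184). The V kappa segments, which are joined to Igkc by rearrangement, held 354, 363 and 496 counts in SF1 replicates 1, 2 and 3 and 29 and 10 counts in WT replicates 1 and 2. Within SF1 replicate 1, 72.6% of these counts were in Igkv4-57 (95% exact Clopper-Pearson interval 67.6 to 77.2%), in SF1 replicate 2 95.6% were in Igkv10-96 (92.9 to 97.5%) and in SF1 replicate 3 92.7% were in Igkv4-63 (90.1 to 94.9%). In WT replicates 1 and 2, Igkv14-111 held 82.8% (64.2 to 94.2%) and 70% (34.8 to 93.3%) of the fewer counts.

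**Figure D3:**
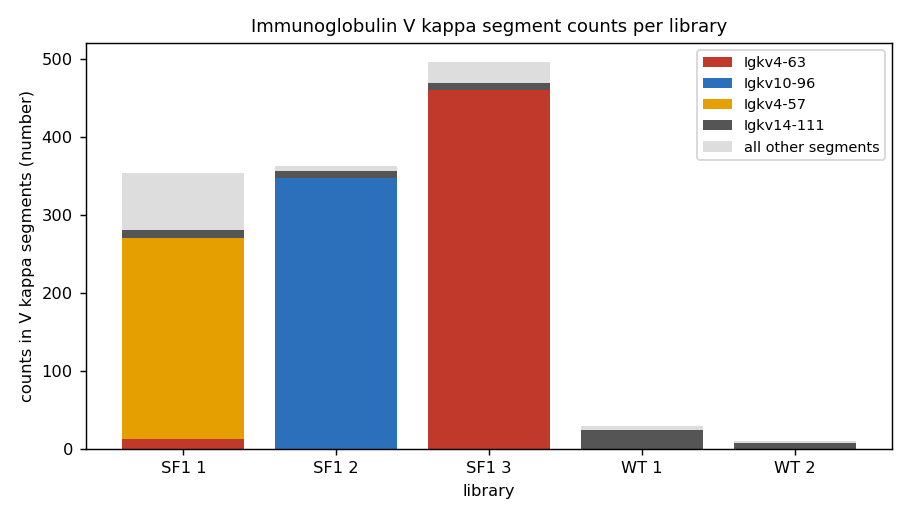
Stacked bars give the number of counts in V kappa segments in each library, coloured by the 4 segments with the most counts over all libraries, with all other segments in light grey. Each SF1 library is led by a different segment (257 counts of Igkv4-57, 347 of Igkv10-96 and 460 of Igkv4-63), and the WT libraries hold 29 and 10 counts, mostly of Igkv14-111.

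Neutrophil and monocyte genes were higher in SF1, with 23 of 28 measured genes higher, none lower and 5 not passing, and also 23 higher when adjusted over the list alone. The granule protein gene Ltf, which encodes lactoferrin (ENSMUSG00000032496, chromosome 9, 111019271 to 111042767), was at 332 ± 207 CPM (SD, n = 3) in SF1 and 15.5 ± 1.47 CPM (n = 2) in WT, a log2 fold change of 4.44 (SE 0.50, adjusted p = 0.001). The calprotectin genes S100a8 and S100a9 rose 21.4-fold and 23.6-fold (adjusted p = 0.00171 for both). These genes varied among the SF1 libraries: S100a9 was at 224, 317 and 876 CPM in replicates 1, 2 and 3. The primary granule protease gene Elane rose 7.70-fold (adjusted p = 0.00568), and Ly86, a monocyte and B-cell surface gene, rose 1.79-fold (adjusted p = 0.000838) with 179, 176 and 189 CPM in the SF1 libraries. The macrophage colony-stimulating factor receptor gene Csf1r rose 2.29-fold (adjusted p = 0.00372). Not passing were Mpo, which encodes myeloperoxidase (857 ± 116 CPM in SF1 and 883 ± 148 CPM in WT, adjusted p = 0.857), the myeloid factors Cebpa and Gfi1 and the cytokine receptor genes Csf3r and Csf2ra. The list was higher by camera (median log2 fold change 2.55, adjusted p = 1.81e-10 with the preset correlation). With the estimated correlation, 0.632 for this list, the adjusted p was 0.612. It had 13 genes higher without WT replicate 1 and 15 without SF1 replicate 2.

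Dendritic cell genes were higher in SF1, with 10 of 17 measured genes higher, none lower and 7 not passing, and 13 higher when adjusted over the list alone. Siglech, a receptor of plasmacytoid dendritic cells, was at 273 ± 55.7 CPM (n = 3) in SF1 and 74.9 ± 9.90 CPM (n = 2) in WT (log2 fold change 1.87, SE 0.18, adjusted p = 0.000443). Irf8, a transcription factor of dendritic cells and monocytes, rose 1.87-fold to 1158 ± 144 CPM (adjusted p = 0.0014), and Cd300c, a myeloid receptor gene, rose 4.28-fold (adjusted p = 0.00316). The list was higher by camera (median log2 fold change 0.81, adjusted p = 1.94e-08), with an adjusted p = 0.533 with an estimated correlation, and had 6 genes higher without WT replicate 1. In the mast cell, basophil and eosinophil list, 3 of 8 genes were higher and 5 did not pass, with 4 higher when adjusted over the list alone (camera adjusted p = 0.121). The eosinophil granule gene Prg2 was at 0.426, 28.6 and 5.88 CPM in the SF1 libraries, against 0.252 and 0.114 CPM in WT (adjusted p = 0.0399; 0.194 without WT replicate 1, 0.106 without WT replicate 2, 0.3 by limma voom). None of this list was called without SF1 replicate 3 or WT replicate 1, and 1 was without WT replicate 2. The list passed as a whole without SF1 replicate 2 (adjusted p = 0.0343) or WT replicate 2 (adjusted p = 0.0474).

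Part of the erythroid and macrophage genes were lower in SF1. Of 17 measured erythroid genes, 8 were lower, none higher and 9 did not pass, with 8 lower and 1 higher when adjusted over the list alone. Car1, a carbonic anhydrase gene of red cell precursors, was at 2.71 ± 0.681 CPM (n = 3) in SF1 and 39.2 ± 11.7 CPM (n = 2) in WT (log2 fold change -3.87, SE 0.25, adjusted p = 0.000117). Of the globin genes, Hba-a2 had no counts in the SF1 libraries against 54 in WT, at least 19.3-fold lower, and Hbb-bs had 1 count against 162, a ratio of 173 (95% counting interval 30.7 to 6890). The list was lower by camera (median log2 fold change -1.27, adjusted p = 0.000656), with an adjusted p = 0.533 with an estimated correlation. Its call was lost with a stricter filter on low counts, where the median was 0.10 (adjusted p = 0.611). Without WT replicate 1, 5 genes were lower and the median was -0.72. Of 15 measured macrophage genes, 7 were lower, 2 higher and 6 did not pass, with 9 and 2 when adjusted over the list alone. Cd5l, a macrophage scavenger receptor family gene, had no counts in SF1 against 41 in WT, at least 14.6-fold lower (adjusted p = 0.00615). The complement gene C1qc was at 1.02 ± 0.331 CPM in SF1 and 4.74 ± 2.64 CPM in WT (adjusted p = 0.0154; 0.0506 without SF1 replicate 2 and 0.111 without WT replicate 2), while the lysosomal gene Cd68 was 2.37-fold higher (adjusted p = 0.00663; 0.0571 without WT replicate 1). The macrophage list was lower by camera (median -1.37, the same with Cd5l at its bound, adjusted p = 0.0154), with an adjusted p = 0.533 with an estimated correlation, and it too was lost with the stricter filter (adjusted p = 0.707). It had 2 genes lower and 1 higher without SF1 replicate 2, 1 lower and none higher without WT replicate 1, and 3 lower and 1 higher without WT replicate 2.

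Part of the natural killer and innate lymphoid genes and a few T-lineage genes were higher in SF1. Of 16 measured natural killer and innate lymphoid genes, 7 were higher and 9 did not pass, with 11 higher when adjusted over the list alone. Klrd1, which encodes the CD94 receptor of natural killer cells, was at 27.7 ± 4.99 CPM (n = 3) in SF1 and 9.04 ± 0.872 CPM (n = 2) in WT (log2 fold change 1.61, SE 0.19, adjusted p = 0.00126). The integrin genes Itgb7 and Itga4 rose 2.64-fold and 1.37-fold (adjusted p = 0.00359 and 0.00568). The list was higher by camera (median 0.57, adjusted p = 0.000993), with an adjusted p = 0.533 with an estimated correlation, and had 4 genes higher without SF1 replicate 2 or SF1 replicate 3 and 3 without WT replicate 1. In the T-lineage list, 3 of 13 genes were higher and 10 did not pass, with 4 higher when adjusted over the list alone (median 0.45, camera adjusted p = 0.0231; adjusted p = 0.533 with an estimated correlation). Cd7, an early T and natural killer cell surface gene, rose from 7.86 ± 2.58 CPM to 37.4 ± 8.79 CPM (adjusted p = 0.00105), and the costimulatory receptor gene Cd28 rose 2.12-fold (adjusted p = 0.00729; 0.0528 without WT replicate 1). Of 7 measured Notch target genes, 1 was lower, Nrarp, a feedback inhibitor of Notch signalling, by 2.86-fold (adjusted p = 0.00189; 2 were lower without SF1 replicate 1), with 2 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.301).

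A few stem cell and megakaryocyte genes were higher in SF1. Of 21 measured stem and multipotent progenitor genes, 4 were higher, 1 (Kit) was lower and 16 did not pass, the same numbers as when adjusted over the list alone. Besides Ly6a, the endothelial and stem cell adhesion gene Esam was higher at a low level, 1.56 ± 0.218 CPM (n = 3) against 0.372 ± 0.0431 CPM (n = 2, adjusted p = 0.0258). The Esam call was lost without SF1 replicate 2 or 3 (adjusted p = 0.0506 and 0.0575) or WT replicate 1 or 2 (0.182 and 0.126), with the replicate number as a block (0.07) and by DESeq2 (0.0576). The list was higher by camera (median 0.20, adjusted p = 0.0266), with an adjusted p = 0.612 with an estimated correlation, and was lost without SF1 replicate 3 (adjusted p = 0.0606) or WT replicate 1 (adjusted p = 0.394). It was also lost with the strict filter (adjusted p = 0.0505) and with the replicate number as a block (0.0782). It had 2 genes higher without SF1 replicate 2 and 1 without SF1 replicate 3 or WT replicate 1. Of 10 megakaryocyte and platelet genes, 4 were higher and 6 did not pass, with 5 higher when adjusted over the list alone (median 1.01, camera adjusted p = 0.00912; adjusted p = 0.612 with an estimated correlation). The platelet integrin gene Itgb3 rose 2.54-fold, to 10.4 ± 0.655 CPM (adjusted p = 0.00405), and the list had 2 genes higher without SF1 replicate 3 or WT replicate 2 and 1 without WT replicate 1. The megakaryocyte median was 0.59 without SF1 replicate 2, 0.38 without SF1 replicate 3, 0.45 with the strict filter and 0.51 with the replicate number as a block. Of 6 stromal and endothelial genes, 2 were higher, 1 lower and 3 did not pass, the same when adjusted over the list alone (camera adjusted p = 0.532), with a median of 0.05 and a mean of -0.09 that differ in sign. None of these was called without SF1 replicate 2, without WT replicate 2 or with the replicate number as a block, 1 was higher and none lower without SF1 replicate 3, and 1 lower and none higher without WT replicate 1.

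Among the genes named for the smallest p-values, those higher in SF1 differed by 1.90-fold to 352-fold and those lower by 2.31-fold to 14.6-fold. Besides the immunoglobulin genes and Ly6d, the higher genes included Smad4, the shared mediator of TGF-beta signalling (25.9 ± 1.82 CPM in WT, n = 2, and 174 ± 32.1 CPM in SF1, n = 3; log2 fold change 2.74, SE 0.17, adjusted p = 9.47e-05). Echdc2, an enoyl-CoA hydratase domain gene, rose 5.66-fold (adjusted p = 8.03e-05), Ybx3, which encodes a nucleic acid-binding cold-shock protein, 7.67-fold (adjusted p = 0.000122), Selenon, a selenoprotein gene, 5.28-fold (adjusted p = 0.000134), and Rab21, an endosomal GTPase gene, 4.54-fold (adjusted p = 0.000196). Gna12, Ankrd11, Sppl3 and Mid1 were also among them, and their exons overlap those of other genes, from which their reads cannot be told apart. Among the lower genes, Tcof1, a ribosomal RNA transcription factor gene, fell 2.75-fold (adjusted p = 0.000106), Nol6, a nucleolar protein gene, 2.55-fold (adjusted p = 0.000162), Cad, which encodes the enzyme that starts pyrimidine synthesis, 2.71-fold (adjusted p = 0.000209), and Ampd2, an AMP deaminase gene with an overlapping neighbour, 2.74-fold (adjusted p = 8.03e-05). Sipa1, a GTPase-activating protein gene, fell 3.25-fold (adjusted p = 0.000162), Emilin1, an extracellular matrix glycoprotein gene, 2.31-fold (adjusted p = 0.000147) and Cluh, an RNA-binding protein gene of mitochondrial metabolism, 2.76-fold (adjusted p = 0.000203). Frmd8, Arap1 and Fbxw8, with overlapping neighbours, and Tcf3 and Car1 complete these lower genes. All of them but Car1 had a GC content between 55.7 and 61.2%, within the range where lower calls were most frequent. After GC and length correction their log2 fold changes were smaller, and each was still called. Tcof1 went from -1.46 to -1.19, Emilin1 from -1.21 to -0.90 and Tcf3 from -1.25 to -0.98.

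Genes of the JAK-STAT pathway moved both ways. Of 21 measured target genes, 5 were higher, 4 lower and 12 did not pass, with 6 and 5 when adjusted over the list alone. The kinase gene Pim2 rose 1.69-fold (adjusted p = 0.00311) and Spred1, an inhibitor of Ras signalling, 2.11-fold (adjusted p = 0.00964). The cyclin gene Ccnd3 fell 1.48-fold (adjusted p = 0.00262), Pim3 1.59-fold (adjusted p = 0.00527) and Myc, the growth-promoting transcription factor gene, from 803 ± 24.4 CPM (n = 2) to 438 ± 104 CPM (n = 3, adjusted p = 0.00663). The feedback inhibitor genes did not pass: Socs3 had a log2 fold change of 0.76 (adjusted p = 0.0589), Socs2 of 0.32 (adjusted p = 0.369), Cish of -0.32 (adjusted p = 0.195) and Socs1 of -0.01 (adjusted p = 0.962), and the kinase gene Pim1 was at 0.01 (adjusted p = 0.961). Socs3 passed as higher without SF1 replicate 1 (0.96, adjusted p = 0.0119), with library-size scaling (0.81, adjusted p = 0.0495), with no filter on low counts (0.74, adjusted p = 0.0063), after GC and length correction (0.85, adjusted p = 0.0454) and by DESeq2 (0.75, adjusted p = 0.0344). The list did not pass (camera adjusted p = 0.762), with a median of -0.01 and a mean of 0.20 that differ in sign, and 3 genes were higher without SF1 replicate 2 or SF1 replicate 3. Of 21 measured pathway components, 2 were higher (Il7r and Cbl, a ubiquitin ligase gene), 4 lower and 15 did not pass, the same when adjusted over the list alone (camera adjusted p = 0.334). Of the 4 lower, the kinase gene Tyk2 went from a log2 fold change of -0.33 to -0.07 after GC and length correction and was no longer called (adjusted p = 0.641). Jak1, Jak3 and Sh2b3 stayed called with smaller changes (-0.31, -0.48 and -0.32). The kinase gene Jak3 fell 1.72-fold, to 111 ± 10.8 CPM (adjusted p = 0.00203), and the negative regulator gene Sh2b3 1.46-fold (adjusted p = 0.00699; 0.0637 without WT replicate 1). Cbl rose 1.30-fold, a call lost without SF1 replicate 2 or 3 or WT replicate 2 (adjusted p = 0.0701, 0.105 and 0.166) or with the replicate number as a block (0.0973). The components lower were 2 without SF1 replicate 2 and 1 without WT replicate 1, and those higher were 1 without SF1 replicate 1 or WT replicate 2 and none without SF1 replicate 2 or 3.

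A few interferon-stimulated genes were lower in SF1, and a few inflammatory response genes were higher. Of 48 measured interferon-stimulated genes, 6 were lower, 3 higher and 39 did not pass, with 11 and 3 when adjusted over the list alone. Ddx58, which encodes the RNA sensor RIG-I, fell 1.76-fold (adjusted p = 0.00404) and the peptide transporter gene Tap1 1.41-fold (adjusted p = 0.00413), while Ly6a and Bst2 were higher (Bst2 adjusted p = 0.0881 without WT replicate 1). The list was lower by camera (median -0.33, adjusted p = 0.00107), with an adjusted p = 0.612 with an estimated correlation, and had 12 genes lower without SF1 replicate 1, 3 without SF1 replicate 2 (median -0.20), and 3 lower and 1 higher without WT replicate 1 (median -0.18). Of 24 TNF and NF-kB response genes, 6 were higher and 18 did not pass, with 7 higher and 1 lower when adjusted over the list alone (median 0.26, camera adjusted p = 0.0154; adjusted p = 0.612 with an estimated correlation). The chemokine gene Ccl3 rose 3.17-fold, to 19.8 ± 6.24 CPM (adjusted p = 0.00485). Only 1 gene of this list was higher without SF1 replicate 2, 2 without SF1 replicate 3 or WT replicate 1, and 3 without WT replicate 2. Of 20 immediate early and dissociation stress genes, 5 were higher and 15 did not pass, the same when adjusted over the list alone (camera adjusted p = 0.0852). The list passed without SF1 replicate 2 (adjusted p = 0.0107) or WT replicate 2 (0.0301), and 3 genes were higher without SF1 replicate 3 and 2 without WT replicate 1. Junb, an AP-1 factor gene, rose 2.05-fold (adjusted p = 0.00713), and Fos was at 27.8, 42.0 and 113 CPM in the SF1 libraries against 9.46 and 9.79 CPM in WT (adjusted p = 0.0124; 0.0837 without WT replicate 1).

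Few antigen presentation and p53 genes passed. Of 11 MHC class II genes, 2 were higher, the peptide-loading genes H2-DMb1 and H2-DMa, and 9 did not pass, the same when adjusted over the list alone. The H2-DMb1 call was lost without WT replicate 1 (adjusted p = 0.1), and the H2-DMa call without SF1 replicates 1, 2 or 3 (adjusted p = 0.0507, 0.103 and 0.0865) or WT replicate 1 (0.232) and with the replicate number as a block (0.0521). The list did not pass (camera adjusted p = 0.334; 0.0341 without WT replicate 2), with a median of -0.04, a mean of 0.001 and an upward test. It had 1 gene higher without SF1 replicate 1, 2 or 3, none higher and 1 lower without WT replicate 1, and 3 higher without WT replicate 2. Of 18 p53 and apoptosis genes, 2 were higher, 1 lower and 15 did not pass, the same when adjusted over the list alone (camera adjusted p = 0.364). The exonuclease gene Aen was 2.00-fold lower (adjusted p = 0.00153), and none of this list was higher without SF1 replicate 2, SF1 replicate 3 or WT replicate 1.

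A few cell cycle and glycolysis genes were lower in SF1, and most did not pass. Of 26 DNA replication genes, 6 were lower and 20 did not pass, with 8 lower when adjusted over the list alone. Uhrf1, which maintains DNA methylation at replication, fell from 592 ± 8.10 CPM (n = 2) to 293 ± 27.4 CPM (n = 3, log2 fold change -1.01, SE 0.09, adjusted p = 0.000371), and the replication licensing gene Cdt1 fell 1.77-fold (adjusted p = 0.00284). The list was lower by camera (median -0.16, adjusted p = 0.00238), with an adjusted p = 0.612 with an estimated correlation, and had 2 genes lower without SF1 replicate 2, SF1 replicate 3 (median -0.10) or WT replicate 1. Of 24 mitotic genes, 4 were lower and 20 did not pass, the same when adjusted over the list alone (median -0.12, camera adjusted p = 0.0458; adjusted p = 0.612 with an estimated correlation). The spindle checkpoint gene Bub1b was 1.30-fold lower (adjusted p = 0.0112; 0.0708 without WT replicate 1). Of 23 glycolysis genes, 5 were lower and 18 did not pass, the same when adjusted over the list alone (median -0.09, camera adjusted p = 0.0458; adjusted p = 0.533 with an estimated correlation). The hexokinase gene Hk1 fell 2.06-fold, to 103 ± 15.4 CPM (adjusted p = 0.00127), and the lactate transporter gene Slc16a1 1.82-fold (adjusted p = 0.00221). The mitotic and glycolysis lists were each lost without SF1 replicate 1 (adjusted p = 0.141 for both), SF1 replicate 2 (0.0703 and 0.0535) or WT replicate 2 (0.484 and 0.0704). The mitotic median was -0.04 without WT replicate 2, and the glycolysis median was -0.14 without WT replicate 1. Both were also lost with library-size scaling (0.112 and 0.0721) and the strict filter (0.141 and 0.115), and the glycolysis list after correction for GC content and length (0.419). The mitotic genes lower were 2 without SF1 replicate 1 or 3 and 1 without SF1 replicate 2, WT replicate 1 or WT replicate 2, and the glycolysis genes lower were 2 without SF1 replicate 1 or WT replicate 1 and 3 without SF1 replicate 2 or 3.

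Few respiratory chain and ribosomal protein genes passed. None of 42 nuclear-encoded respiratory chain genes and none of 10 mitochondrially encoded genes passed by edgeR, over all genes or adjusted over the list alone (camera adjusted p = 0.349 and 0.0595). By edgeR 3 and 1 of them had an unadjusted p under 0.05, and none passed by limma voom or DESeq2. Both lists were higher without WT replicate 2 (adjusted p = 0.0332 and 0.000974), and the mitochondrially encoded list was also higher with the replicate number as a block (median 0.19, adjusted p = 0.0366). The mitochondrially encoded list had 1 gene higher without WT replicate 2. The mitochondrially encoded oxidase subunit gene mt-Co1 was at 701 ± 10.4 CPM (n = 3) in SF1 and 630 ± 90.6 CPM (n = 2) in WT (adjusted p = 0.286). Of 57 cytosolic ribosomal protein genes, 2 were higher, among them Rps14 by 1.20-fold (adjusted p = 0.0469), and 55 did not pass, with none passing when adjusted over the list alone. The Rps14 call was lost without SF1 replicate 1, 2 or 3 (adjusted p = 0.099, 0.063 and 0.127) or WT replicate 1 or 2 (0.16 and 0.148), with DESeq2 size factors (0.0527), with the replicate number as a block (0.111) and after GC and length correction (0.0591). The list was higher by camera (median 0.07, adjusted p = 0.0104), with an adjusted p = 0.687 with an estimated correlation. It turned downward without WT replicate 1 (median -0.04, adjusted p = 0.56) and was lost without SF1 replicate 1 (median 0.03, adjusted p = 0.163) and after correction for GC content and length (adjusted p = 0.82). Its median was 0.13 without SF1 replicate 2 and 0.19 without WT replicate 2, and none of its genes was called without SF1 replicate 1, 2 or 3 or WT replicate 1, and 1 was without WT replicate 2.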

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

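The GC and length correction and the thinning to equal totals were chosen after the data were seen. The number of changed genes (2382) stayed within 1.5 times under the other scalings, filters and tools. With the replicate number as a block it was 1519, of them 574 higher, in a fit where SF1 replicate 3 has no WT partner and adds nothing to the fold change. Same-numbered SF1 and WT libraries deviated together with r of 0.036 and 0.065 across genes, over only 2 shared numbers, which gives no sign of pairing. Leaving out 1 library gave between 986 and 2170 changed genes, between 464 and 905 of them higher and between 522 and 1265 lower. Fewer libraries account for part of this, and the rest of the cause was not tested. Higher genes made up 41% of the calls, and 50.7% with library-size scaling. Of the 15 lists called, 0 passed with an estimated correlation and 3 by fry (dendritic, erythroid and glycolysis genes), and none kept its call under all alternatives. Of 172 called genes named by the rule or in a list, 80 kept direction and call under each alternative that tested them, and none changed sign. Since the SF1 and WT libraries did not overlap in any called gene, leaving out 1 library could hardly change a sign. The lack of such changes is therefore not a separate check.

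Lists whose camera direction reversed are given by their median log2 fold changes. Without WT replicate 1 these were the ribosomal protein (-0.039), MHC class II (-0.157) and mitochondrially encoded genes (-0.011), highest at 0.186, 0.225 and 0.378 without WT replicate 2. The JAK-STAT targets were at -0.055 without SF1 replicate 2 and -0.114 without WT replicate 1 (highest 0.122). The respiratory chain genes were at -0.025 without WT replicate 1 and -0.05 after GC and length correction (highest 0.116). The stromal genes were at -0.087 and -0.375 without WT replicates 1 and 2, against 0.097 without SF1 replicate 3 and 0.118 after GC and length correction. The medians of MHC class II and of the JAK-STAT targets were below 0 with all libraries too (-0.038 and -0.007), and the stromal median was also below 0 without SF1 replicates 1 and 2 (-0.138 and -0.089). Reversed genes, all uncalled, were mt-Cytb (-0.011 after the correction), mt-Nd2 (-0.036 without WT replicate 1, highest 0.396), Pim1 (-0.003 with no filter, -0.098 without SF1 replicate 2, -0.194 without WT replicate 1, highest 0.229) and Socs1 (0.03 with library-size scaling, 0.007 with the strict filter, 0.004 with the block, 0.075 after the correction, 0.028 with voom, 0.018 with voom and weights, 0.03, 0 and 0.144 without SF1 replicates 2 and 3 and WT replicate 2, lowest -0.182). The cause was not tested.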

Other observations

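All tests of explanations below were chosen after the results were seen. A group of neighbouring transcripts at the distal end of the X chromosome was present in SF1 and nearly absent in WT. Mid1, a ubiquitin ligase gene (X, 169685199 to 170005736), was at 11.5 ± 2.82 CPM (SD, n = 3) in SF1 and 0.24 ± 0.0168 CPM (n = 2) in WT. G530011O06Rik, which starts at 169975043 and overlaps it, had 727 counts in SF1 and 3 in WT, a ratio of 226 (95% counting interval 77.2 to 1100), and the overlapping gene Gm15247 had 164 counts in SF1 and none in WT, at least 51.1-fold higher (3 counts over the group). Reads of these overlapping genes cannot be told apart, and a strain difference at this locus, which would give the same values without an effect of the mutant, could not be tested from counts. Neutrophil genes outside the lists rose as well: Lcn2, which encodes lipocalin 2, 27.1-fold (adjusted p = 0.00176), Cd177, a neutrophil surface gene, 19.9-fold (adjusted p = 0.00206) and Chil3, a chitinase-like gene, 14.0-fold (adjusted p = 0.00696). These genes were named after their values were seen.

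The rise of neutrophil and monocyte genes may come from granulocytic RNA in the sorted SF1 libraries, although the sort excludes lineage-positive cells, and the tests do not decide it. Such a source would raise all its genes by a common factor in each library. The test used 21 called genes of the fixed list, none in another list and all with counts in both WT libraries. Their excess over WT in SF1 replicate 3 was between 1.13 and 13.8 times that in replicate 1, and 18 of 21 ordered the libraries alike. The most abundant of them, Ngp, was at 313, 459 and 1204 CPM. The list also holds monocyte genes, so this range does not test granulocytic genes alone. The lowest ratio was that of Ly86, with an excess of 77.5 and 87.3 CPM in SF1 replicates 1 and 3. The excess of S100a8 went from 195.6 to 796.7 CPM and that of Ngp from 279.8 to 1170.5 CPM. Elane went from 78.3 to 157.5 CPM and Fcnb from 3.5 to 47.7 CPM. The excess of 10 dendritic genes had a median slope of 0.37 on that of the 21 genes (log2 scale), which had 0.98 with an SD of 0.50 among themselves. The slopes of the 21 genes ran from 0.1 to 2.15, which makes this SD wide. Of the 10 dendritic genes, 5 ordered the libraries as the 18 did. Their median ratio of replicate 3 to replicate 1 was 1.64, against 3.40 for the 21 genes. The dendritic slope lies below by less than that SD plus 2 times the error of the median, the bound set for the test, so a common source is left open. Earlier versions of these tests rested on 9 granule genes picked from these libraries and were dropped. A lower share of gated cells with an unchanged mix of other cells would raise all other markers alike. The median of the neutrophil and monocyte genes lay 3.82 above that of the erythroid genes (error of the difference 0.88). This error was taken over genes, so it does not measure the spread between libraries. With the strict filter on low counts the medians were 2.22 and 0.10. The values argue against an even rise of all other markers. A lower share with a changed mix of other cells was not tested. The test of medians replaced an earlier one on the erythroid median alone, which could not tell. A myeloid programme within SF1 progenitors remains open and was not tested, since bulk counts do not locate RNA in cells.

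The immunoglobulin rise is consistent with RNA of a few antibody-producing cells in each SF1 library, since 1 segment held at least 72.6% of its V kappa counts and a different one led in each. Such a share alone does not set SF1 apart, as Igkv14-111 held 82.8 and 70% of the 29 and 10 counts in the WT libraries. There the same segment led in both, and it was not specific to WT. It had 11, 9 and 9 counts in the SF1 libraries, against 24 and 7 in WT replicates 1 and 2. Igkv4-57, Igkv10-96 and Igkv4-63, each leading 1 SF1 library, had 0 counts in both WT libraries. The leading SF1 segments, rather than the share, therefore set SF1 apart. The heavy chain V segments differed less, at 132, 128 and 149 CPM in SF1 and 123 and 130 in WT, though Ighv1-81 had 48, 257 and 603 counts in the SF1 libraries and 105 and 35 in WT replicates 1 and 2. Such cells would be expected to be removed by the lineage stain or to lack Flt3, and the plasma cell gene Mzb1 stayed at 0.813 CPM in SF1, so free RNA, a few cells and a difference between the animals remain open. Transcription of the unrearranged kappa locus in the gated cells can give Igkc without a V segment. Summed V kappa CPM were 29.1-fold higher in SF1, however, and the lowest SF1 library was at 22.6 times the highest WT library. Igha and Jchain, which are not part of that locus, rose by 8.46 and 5.66 on the log2 scale. These values argue against such transcription as the only source of the rise, and its share in Igkc was not tested.

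Genes lower in SF1 were more frequent among GC-rich and among long transcripts: 300 genes were lower and 67 higher in the highest 10% by GC content (57.6 to 82.9%), against 44 and 102 in the lowest, and 202 were lower and 111 higher in the longest 10%, against 36 and 84 in the shortest (Spearman correlation of the fold change -0.152 with GC and -0.194 with length). A GC or length bias of the libraries may have added to the lower calls. The trend that the correction removed is argued against as their whole cause. With it removed, 74.2% of the 1405 lower genes were called lower again (remaining correlations -0.072 and -0.027), including all 10 lower B-lineage genes. The correction left a GC gradient in the calls, with 199 genes lower and 93 higher in the highest 10%, against 61 and 85 in the lowest. How well it works on these libraries is not known, so a bias that it misses is not excluded. Within the highest 10% by GC, 193 of the 300 stayed called. Depth is argued against as well, with 92% of the lower genes called again after thinning to equal totals. A change in the expression of GC-rich or long genes with the genotype remains open as a hypothesis, and the libraries' SMART-Seq version, which could differ between them, was not available to test.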
